A study of Homo sapiens with 41 samples.

How the data were processed

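RNA was measured in naive CD4+ T cells sorted from cord blood and adult blood, before activation (0 h) and 3, 24 and 48 h after it, as poly-A-selected, paired-end Illumina libraries made with random-hexamer priming. The labels do not say whether the libraries were directional. They say that samples which failed RNA quality control were not sequenced, so the 41 libraries are those that passed. Donor numbers in the labels link libraries of the same donor at different times, and cord and adult donors are different people.

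Per the submitters' processing notes, the authors quantified the reads with kallisto 0.46.2 against a GRCh38 (hg38) transcriptome. The deposited tables list 273426 transcripts per library, with estimated counts that the authors did not normalise, the TPM that kallisto derived from them (per effective length and per library total), and each transcript's effective length. The annotation release, the index and the kallisto options are not given in the sources used here. Transcripts were matched to genes by their identifiers, without the version number, in GENCODE release 29, which may not be the authors' annotation. The match covered 201685 transcripts (73.8%) and 86.9 to 90.7% of each library's estimated counts, in 57462 genes, and unmatched transcripts were left out of the gene sums. XIST, TSIX and genes on the Y chromosome (513 genes) were left out of every test.

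Estimated counts were summed by gene and rounded. Library totals ran from 13459270 to 32872384 with a median of 20937879. Genes were filtered with edgeR's filterByExpr over the 8 groups (minimum count 10, minimum total count 15), which left 23190 genes, 15058 of them protein coding. Counts were normalised with TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 41 libraries (edgeR 4.0.16, glmQLFit with robust estimation, glmQLFTest). Its common biological coefficient of variation was 0.342. There were 13 comparisons: cord against adult at each of 4 times, each later time against 0 h in each source, and the difference of these changes between the sources. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, and the tests are two-sided.

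Gene lists, 38 in number, covered metabolism, T cell states and lineages, signalling and stress, development and markers of other cells. They were tested as groups against all other genes with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted within a comparison over the 34 lists with at least 5 tested members. The lists of CD8 T cell, dendritic cell, granulocyte and progenitor markers had fewer and were compared as summed CPM. Members were also counted with their p-values adjusted over the list alone. CD38 was compared with exact two-sided permutation tests of log2 CPM, and summed markers of other cells (CPM) and shares of a library's counts, such as mitochondrial rRNA, with the same test on their own scale. These designs, the lists, the alternatives and the rule for naming genes were fixed before the data were examined, apart from the later choices that are said below to be so.

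The rule named, in each comparison of the sources, the 10 genes with the largest and the 10 with the smallest log2 fold change among those called with a log2 change of at least 1, at least 5 CPM in the higher group and no overlap between the groups. For changes with time it named 5 in each direction with at least 20 CPM, and for the difference of changes 5 in each direction with at least 5 CPM and no condition on overlap. It added CD38 and up to 4 members of each list described. HLA, KIR, immunoglobulin and T cell receptor genes were not named, and other genes of the MHC region (chromosome 6, 28510000 to 33480000) were left unnamed too, a choice made after the data were seen. The text gives part of these genes, and those from outside the rule are said to be so.

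Alternatives were RLE size factors, no count filter, DESeq2 1.42.0, limma on log2 TPM, counts scaled by transcript length, a fit on the groups compared alone, each library left out in turn, and a replicate block. The block compared times within donors (a donor term in edgeR) and, between sources, took donors as a random effect in limma-voom. For the list tests they were an estimated correlation and fry. Of these, limma-voom with no block and a fit without 6 libraries with outlying CD8, erythroid or monocyte markers were chosen after seeing the data. The numbers pairing libraries by donor came from the labels. After group means were removed, libraries with the same donor number correlated across genes (mean r 0.383 over 24 cord pairs and 0.441 over 17 adult pairs), and libraries of different donors did not on average (-0.064 and -0.055).

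Data were simulated with the groups and depth of these libraries, each library drawn independently from 1 mean and 1 spread per gene. Changed genes were taken from those with a mean of at least 5 CPM. On these data edgeR recovered 76% of 2-fold and 96% of 4-fold changes between the sources at 24 h, with 6 false calls among 22077 genes. It made 0 calls where no gene was changed. The simulation held no donor effects and no other differences between times or sources, so rates in the real data may differ. For the difference of changes at 24 h it recovered 56% of 2-fold and 89% of 4-fold changes, and DESeq2 recovered 65% and 94% with 24 false calls against 10. Folds against a group without counts are lower bounds computed from 3 counts over the group, and such bounds cover counting error only. Other software was R 4.3.3, the package data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.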

Results

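Messenger RNA was sequenced from naive CD4+ T cells of umbilical cord blood and of adult blood, at rest (0 h) and 3, 24 and 48 h after activation with soluble antibodies to CD3 and CD28, which engage the T cell receptor complex and its main costimulator. Cord blood gave 6 libraries at 0 h and 5 at each later time, and adult blood gave 5 at every time, 41 libraries in all. Each library held between 13459270 and 32872384 estimated counts, with a median of 20937879, and group medians ran from 18355992 to 24400781. The donors sampled at 0 and 3 h were in part other people than those sampled at 24 and 48 h, so a difference between times also holds differences between donors. None of the libraries is labelled as cultured without the antibodies, so changes from 0 h cannot be told apart from effects of culture. Levels are CPM, counts scaled to a common library total after TMM normalisation, as mean ± SD over the libraries of a group. Log2 fold changes are given with their SE from edgeR's quasi-likelihood test, and adjusted p-values are two-sided Benjamini-Hochberg values over the 23190 genes tested, unless stated otherwise. The comparisons address how naive cells from birth and from adulthood differ in CD38, in metabolic genes and in genes of regulatory T cells, at rest and after activation.

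Time and source both ordered the libraries. Principal component 1 carried 62.0% of the variance and ran from resting cells to cells at 48 h. Principal component 3 carried 6.4% and parted the sources at every time, with every adult library above 0 and every cord library below 0.

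**Figure D1:**
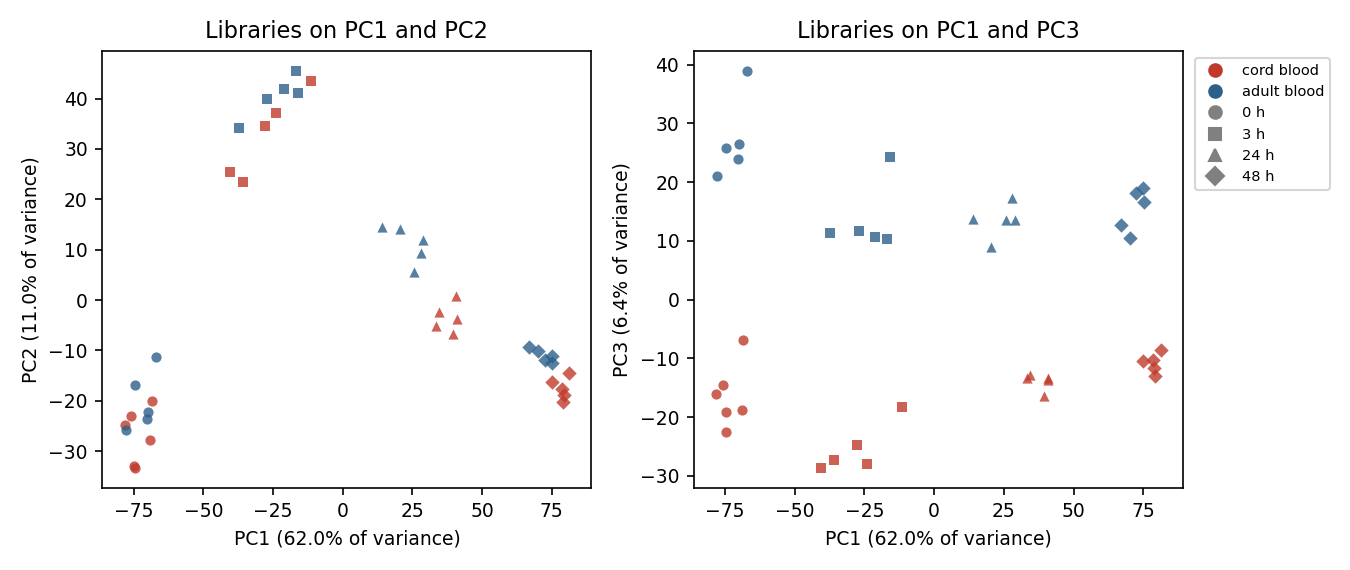
Each point is a library, placed by its scores on principal components 1 and 2 (left) and 1 and 3 (right), coloured by source and shaped by hours after activation. Component 1 (62.0% of the variance) follows time, and component 3 (6.4%) separates cord from adult libraries.

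CD38, an enzyme that hydrolyses NAD at the cell surface, was most abundant in resting cord cells and differed between the sources at 0 and 3 h. The gene (chromosome 4, 15778275 to 15853230 of GRCh38) stood at 60.2 ± 14.5 CPM in resting cord cells (n = 6) and at 19.4 ± 7.44 CPM in resting adult cells (n = 5), a 3.10-fold difference. At 3 h the levels were 26.0 ± 6.09 CPM in cord and 12.7 ± 2.71 CPM in adult cells (n = 5 each), 2.04-fold apart, and the cord level had dropped (log2 change -1.21 ± 0.27, adjusted p = 0.000427). By 24 h CD38 stood at 38.9 ± 6.00 CPM in cord and 27.9 ± 17.8 CPM in adult cells, and by 48 h at 45.4 ± 13.2 and 34.9 ± 6.44 CPM. Adult cells had gained CD38 by 48 h against rest (0.85 ± 0.28, adjusted p = 0.00836). The source difference passed the test at 0 h (1.63 ± 0.27, adjusted p = 3.27e-05) and at 3 h (1.03 ± 0.28, adjusted p = 0.011), and not at 24 h (0.48 ± 0.28, adjusted p = 0.365) or 48 h (0.38 ± 0.28, adjusted p = 0.598). A two-sided exact permutation test of the log2 CPM gave p = 0.00433 at 0 h and p = 0.00794 at 3 h, each the smallest possible, and p = 0.143 at 24 h and p = 0.151 at 48 h, which adjusted over the 4 times to 0.0159, 0.0159, 0.151 and 0.151. The mean differences in log2 CPM were 0.68 at 24 h and 0.34 at 48 h. Without adult replicate 3 the former was 0.98, and without cord replicate 5 the latter was 0.49, and each then passed (exact test, adjusted p = 0.0423). In log2(TPM + 1) they were 0.14 and 0.17 (exact test, adjusted p = 0.77 each), and the TPM at 24 h was 11.4 ± 1.90 in cord and 11.7 ± 8.17 in adult cells. On TPM the 3 h call was just missed by limma (0.86, adjusted p = 0.0504).

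**Figure D2:**
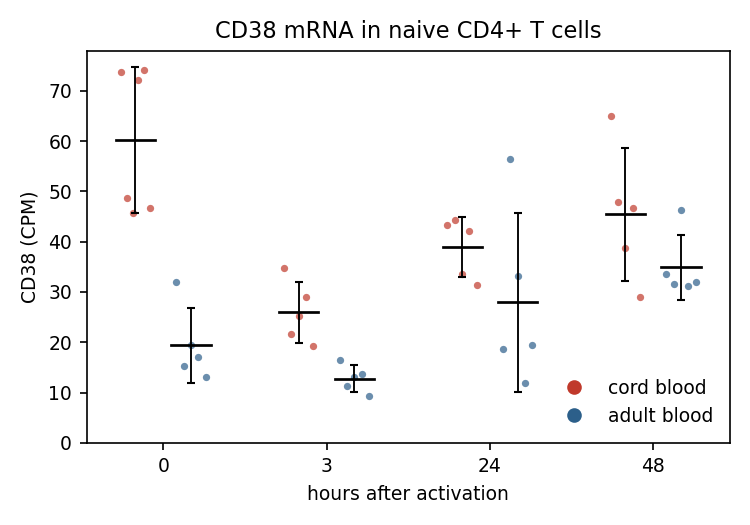
CD38 in CPM (vertical axis) against hours after activation (horizontal axis); each point is a library, lines are group means and bars 1 SD. Cord libraries average 60.2 CPM at rest against 19.4 CPM in adult libraries, and the groups overlap at 24 and 48 h.

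At rest, cord cells carried transcripts of the fetal programme and of recent thymic emigrants that were scarce in adult cells. IGF2BP3, an RNA-binding protein controlled by LIN28B and let-7, stood at 48.5 ± 5.43 CPM in cord (n = 6) against 1.35 ± 0.112 CPM in adult cells (n = 5), a 35.8-fold difference. AUTS2, which works with Polycomb complexes, stood at 169 ± 31.6 against 5.14 ± 1.19 CPM, and the Polycomb member CBX2 at 20.8 ± 2.83 against 0.934 ± 0.785 CPM. In the other direction, the zinc-finger factor TSHZ2 stood at 0.431 ± 0.367 CPM in cord and 156 ± 33.8 CPM in adult cells, a 349-fold difference, and NR3C2, the mineralocorticoid receptor, at 0.538 ± 0.451 and 30.4 ± 3.76 CPM. MIRLET7BHG, the host transcript of let-7 microRNAs, stood at 0.193 ± 0.0866 against 5.37 ± 2.04 CPM.

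Among 22 tested genes of the LIN28B-let-7 programme, 8 were higher and 1 lower in resting cord cells (9 and 1 adjusted over the list alone), and the list as a whole was higher (camera adjusted p = 1.67e-07). BCL11A, a repressor of fetal globin genes in red cells, led with IGF2BP3 (4.27 ± 0.32, adjusted p = 1.13e-12). Of 18 recent thymic emigrant genes 9 were higher and none lower (also 9 and 0 adjusted over the list alone, camera adjusted p = 2.67e-11), among them SOX4 (2.92 ± 0.45) and ADAM23 (3.93 ± 0.57). That list shares BCL11A with the let-7 list, CD38 with the NAD list and IKZF2 with the regulatory T cell list. Of 13 Th1 genes 5 were lower and none higher (6 and 0 adjusted over the list alone, camera adjusted p = 0.000149), led in certainty by STAT4, which transmits IL-12 signals (-1.88 ± 0.19, adjusted p = 9.99e-10).

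Regulatory T cell genes were divided at rest. IKZF2, which encodes Helios, stood at 124 ± 13.6 CPM in cord against 13.2 ± 5.95 CPM in adult cells, while IL2RA, the high-affinity IL-2 receptor chain (-2.43 ± 0.26, adjusted p = 5.52e-09), and CTLA4, an inhibitory receptor (-2.54 ± 0.31, adjusted p = 1.43e-07), were lower in cord. FOXP3, the lineage factor of regulatory T cells, was also lower, at 8.23 ± 3.15 against 22.9 ± 8.82 CPM (adjusted p = 0.000703). It lies outside the rule for named genes and was chosen after its values were seen. Of the 24 tested members 3 were higher and 9 lower (4 and 10 adjusted over the list alone), and the list was lower by camera (adjusted p = 0.00414), a call lost at adjusted p = 0.206 with an estimated correlation.

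Resting metabolic genes differed in single members more than as groups. Of 30 NAD genes, CD38 and PARP2 were higher and SARM1, another NAD hydrolase, was lower in cord (-1.30 ± 0.09, adjusted p = 8.79e-14). The counts were also 2 and 1 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.481). Of 25 glycolysis genes 1 was higher, the hexokinase HK1 (0.84 ± 0.13), and 7 were lower, among them the glucose transporter SLC2A3 (-1.14 ± 0.19) and the enolase ENO2 (47.6 against 95.3 CPM, adjusted p = 6.3e-07). Adjusted over the list alone it was 1 and 8. The glycolysis list was lower by camera (adjusted p = 0.029) but not at adjusted p = 0.696 with an estimated correlation, nor without the 6 libraries with outlying markers of other cells. Nuclear genes of oxidative phosphorylation showed 2 higher and 2 lower of 77 (1 and 1 adjusted over the list alone, camera adjusted p = 0.511).

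Single stress, early-activation and interferon genes were lower in resting cord cells, and none of the 3 lists passed with an estimated correlation. Of 15 heat shock genes 6 were lower, such as the chaperone HSPD1 (-0.86 ± 0.13), and 9 when adjusted over the list alone (camera adjusted p = 0.000143, and adjusted p = 0.502 with an estimated correlation). Of 35 immediate early and NR4A genes 2 were higher and 9 lower (2 and 10 adjusted over the list alone), with NR4A2 at 3.96 ± 3.47 against 36.0 ± 29.7 CPM (camera adjusted p = 0.0174, and adjusted p = 0.696 with an estimated correlation). Of 42 interferon-stimulated genes 6 were lower, also adjusted over the list alone, such as BST2, which tethers virions (-2.24 ± 0.47, camera adjusted p = 9.39e-05, and adjusted p = 0.696 with an estimated correlation).

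Summed markers of some other cell types differed between the sources at rest, and a sum follows its most abundant members. Summed markers of NK and cytotoxic cells stood at 85.9 ± 17.2 CPM in cord against 32.9 ± 10.8 CPM in adult libraries, those of dendritic cells at 29.3 ± 3.20 against 8.41 ± 2.20 CPM, and those of CD8 T cells at 10.8 ± 3.60 against 4.30 ± 2.38 CPM (adjusted p = 0.0396 each, exact two-sided permutation tests, 64 in the family, smallest possible unadjusted p = 0.00433). At the same adjusted p, granulocyte markers stood at 4.99 ± 2.00 against 2.22 ± 0.535 CPM and the fetal haemoglobin genes HBG1 and HBG2 at 3.81 ± 1.72 against 0.939 ± 0.451 CPM. FGFBP2, a secreted protein of cytotoxic cells, and the granzyme GZMA were 36.0-fold and 24.0-fold higher in cord. Both belong to the summed NK and cytotoxic list, at 27.0 ± 12.7 and 15.4 ± 3.36 CPM in cord. The other 11 tested members of that list had a median log2 difference of -1.52, so the higher sum does not stand for the list as a whole. Of these 11, GNLY alone was called (-1.91 ± 0.54), while KLRD1 (0.17 ± 0.27), PRF1 (0.29 ± 0.425) and SPON2 (0.68 ± 0.24) lay above 0. The median so rests in part on members with a large SE, such as GZMB (-4.96 ± 1.84) and GZMH (-1.96 ± 1.35). The test called 3113 of the 23190 genes at 0 h, 1376 higher and 1737 lower in cord. A fit on the resting libraries alone called 1754, and limma on TPM placed 61.5% of its calls higher against 44.2% here.

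At 3 h the fetal transcripts still set the sources apart, and cord cells had gained IL2RA past the adult level. IGF2BP3 was 266-fold higher in cord, against 0.928 ± 0.260 CPM in adult cells (n = 5 each). DAPK1, a death-associated kinase, stood at 79.8 ± 20.4 against 1.85 ± 0.742 CPM, and the tight-junction protein CLDN1 at 75.3 ± 38.6 against 1.87 ± 0.513 CPM. TSHZ2 (0.449 ± 0.301 against 78.3 ± 16.2 CPM) and KIF21A, a kinesin (1.64 ± 0.277 against 47.5 ± 10.4 CPM), were lower in cord. ICOS, a costimulatory receptor, was higher in cord at 742 ± 158 against 209 ± 34.5 CPM.

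The LIN28B-let-7 list was higher in cord at 3 h with 5 members up and none down (also 5 and 0 adjusted over the list alone, camera adjusted p = 1.5e-06). So was the recent thymic emigrant list, with 8 up and 1 down (9 and 1 adjusted over the list alone, camera adjusted p = 1.05e-06). PTK7, an emigrant marker, stood at 27.1 ± 5.72 CPM against 3.59 ± 1.63 CPM. Regulatory T cell genes split into 7 higher and 4 lower (7 and 8 adjusted over the list alone), with a median of -0.32, a mean of -0.03 and an upward test direction that did not pass (camera adjusted p = 0.601). Th1 genes had 4 lower and none higher (6 and 0 adjusted over the list alone), such as STAT4 (-1.27 ± 0.20). The list was lower (camera adjusted p = 0.00168), with adjusted p = 0.0526 with an estimated correlation. Of the glycolysis genes 1 was higher and 6 lower, also when adjusted over the list alone, led by ENO2 (-1.33 ± 0.14, camera adjusted p = 0.0156, and adjusted p = 0.693 with an estimated correlation). Heat shock genes had 2 lower (8 adjusted over the list alone, camera adjusted p = 0.00582, and adjusted p = 0.693 with an estimated correlation). BST2 alone of the interferon-stimulated genes was lower, also over the list alone (camera adjusted p = 0.00168, and adjusted p = 0.902 with an estimated correlation). The NAD list did not pass (camera adjusted p = 0.602, with a median of 0.00, a mean of 0.02 and a downward test direction), with 2 higher and 2 lower (3 and 3 adjusted over the list alone) and SARM1 again lower (-1.36 ± 0.10).

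The test called 2574 genes at 3 h, 1283 higher and 1291 lower in cord. On TPM limma called 1653, and a fit on the 3 h libraries alone called 1381. Mitochondrial rRNA took 0.363% ± 0.0562 of the counts in cord and 0.220% ± 0.0587 in adult libraries (exact permutation test, adjusted p = 0.0396).

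At 24 h cord cells had more cell cycle transcripts than adult cells. Of 45 cell cycle genes 33 were higher and 1 was lower in cord (37 and 1 adjusted over the list alone, camera adjusted p = 3.24e-34), with TYMS, which makes thymidylate, at 135 ± 23.2 against 28.0 ± 7.82 CPM (n = 5 each) and the mitotic cyclin CCNB2 at 4.71 ± 0.863 against 1.23 ± 0.274 CPM. The proliferation marker MKI67 was also higher (2.27 ± 0.32, adjusted p = 6.23e-06), though not with counts scaled by transcript length. The lower member was CDKN1B, an inhibitor of cyclin-dependent kinases (chosen after its value was seen, -0.54 ± 0.15). Of 18 genes of serine and one-carbon metabolism 6 were higher and none lower (7 and 1 adjusted over the list alone, camera adjusted p = 7.52e-05), among them PHGDH, which begins serine synthesis (53.2 ± 4.15 against 20.8 ± 3.41 CPM).

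At 24 h 2 mitochondrial lists were higher in cord by camera at its preset correlation and not with an estimated one, and of these the TCA cycle list also passed fry (adjusted p = 0.0265). Of 77 nuclear genes of oxidative phosphorylation 1 was higher (0 adjusted over the list alone), and the median was 0.25. The list was higher by camera (adjusted p = 5.64e-06) and not at adjusted p = 0.561 with an estimated correlation. Of 25 TCA cycle genes 3 were higher, also adjusted over the list alone, led by IDH2 (0.82 ± 0.16, camera adjusted p = 0.0014, and adjusted p = 0.43 with an estimated correlation). The NAD list did not pass (camera adjusted p = 0.633), with 3 members higher and 2 lower, also adjusted over the list alone, and SARM1 lower (-1.02 ± 0.10).

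Recent thymic emigrant genes were higher in cord at 24 h, and regulatory T cell genes did not pass as a list. CD1C, an antigen-presenting molecule of immature thymocytes, stood at 13.5 ± 3.71 CPM in cord against 0.264 ± 0.181 CPM in adult cells, and CD93 at 18.2 ± 4.17 against 0.350 ± 0.179 CPM. The mean of CD1C was 0 CPM at rest in both sources, so its level at 24 h was not carried over from rest. In adult cells it reached 6.43 ± 3.205 CPM at 48 h. Of the emigrant genes 10 were higher and none lower (10 and 0 adjusted over the list alone, camera adjusted p = 6.28e-18). Of the let-7 genes 7 were higher and 1 lower (9 and 1, camera adjusted p = 7.69e-11). LRRC32, which encodes the TGF-beta carrier GARP, stood at 33.7 ± 15.2 against 6.41 ± 2.81 CPM, and the regulatory cytokine IL10 was higher (2.84 ± 0.67, adjusted p = 0.00423). In all, 6 regulatory T cell genes were higher and 2 lower (7 and 4 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.261).

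Th1 and Th17 genes were lower in cord at 24 h. Th1 genes had 4 lower and none higher, also over the list alone, with the chemokine receptor CXCR3 at 2.96 ± 1.42 against 13.5 ± 9.71 CPM (camera adjusted p = 0.000315). Th17 genes had 3 lower and none higher, also over the list alone, led by RORA (-1.09 ± 0.16, camera adjusted p = 0.00746). NF-kB and survival genes had 6 lower (1 higher and 9 lower adjusted over the list alone) such as TRAF1 (-0.75 ± 0.19, camera adjusted p = 8.07e-05, and adjusted p = 0.415 with an estimated correlation). Immediate early genes had 1 higher and 5 lower (1 and 8 over the list alone) such as JUN (-1.92 ± 0.46, camera adjusted p = 0.000107, and adjusted p = 0.5 with an estimated correlation).

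Summed CD8 T cell markers stood at 33.3 ± 21.6 CPM in cord against 6.37 ± 3.00 CPM at 24 h, and B cell markers at 32.5 ± 3.89 against 21.7 ± 1.70 CPM (adjusted p = 0.0396 each, exact permutation tests). Mitochondrial rRNA took 0.351% ± 0.0144 of the counts in cord and 0.196% ± 0.0455 in adult libraries (same test and adjusted p). HBA2, a globin of red cells, was named by the rule through RNA of red cells in cord replicate 5. The test called 1897 genes, 1147 higher and 750 lower in cord, a share of 60.5% higher. With limma on TPM 1243 were called and 34.9% were higher, length-scaled counts gave 1130, and a fit on the 24 h libraries alone gave 2902.

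At 48 h cord cells expressed Th2 genes at higher levels than adult cells. IL13, against 1.70 ± 0.668 CPM in adult cells, was higher in cord by 4.24 ± 0.54 (log2, n = 5 each). Its lineage factor GATA3 stood at 237 ± 53.9 against 48.6 ± 10.2 CPM, and MAF at 82.3 ± 30.2 against 25.7 ± 4.30 CPM. Of 12 Th2 genes 5 were higher and none lower (8 and 1 adjusted over the list alone, camera adjusted p = 7.85e-10). IL2 was lower in cord at 107 ± 44.7 against 318 ± 95.3 CPM (adjusted p = 0.00347), and IL21, a cytokine of follicular help, at 3.96 ± 1.89 against 35.8 ± 20.2 CPM.

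Sterol genes were also higher in cord at 48 h. Of 24 cholesterol synthesis genes 12 were higher and none lower (18 and 0 adjusted over the list alone, camera adjusted p = 5.7e-18), such as the sterol carrier STARD4 (1.06 ± 0.15) and MVD, which makes isopentenyl pyrophosphate (1.00 ± 0.17). No gene of oxidative phosphorylation passed, also over the list alone, while the list's median was 0.23 and camera called it higher (adjusted p = 1.31e-06, and adjusted p = 0.477 with an estimated correlation). UQCRC2, a complex III subunit, passed with a replicate block (0.35, adjusted p = 0.032). SARM1 was the NAD gene that passed (-1.28 ± 0.10, also over the list alone), and the NAD list did not (camera adjusted p = 0.0895).

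Recent thymic emigrant genes were again higher in cord at 48 h, beside single regulatory T cell genes. LRRC32 stood at 44.2 ± 14.8 against 6.11 ± 2.07 CPM and IL10 at 35.8 ± 19.1 against 2.50 ± 1.82 CPM. In all, 4 regulatory T cell genes were higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.0224, and adjusted p = 0.215 with an estimated correlation). FOXP3 did not differ past the test at 3, 24 or 48 h (adjusted p = 0.285, 0.78 and 0.301). Of the emigrant genes 10 were higher and none lower, also over the list alone (camera adjusted p = 6.94e-20), with SOX4 at 59.5 ± 9.13 against 4.11 ± 1.94 CPM. Of the let-7 genes 6 were higher and none lower (9 and 1 over the list alone, camera adjusted p = 2.19e-15). Th17 genes had 4 lower (1 higher and 5 lower over the list alone), such as RORA (-1.33 ± 0.16, camera adjusted p = 0.00529).

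Differentiation genes moved as well. Of 28 memory and effector genes 10 were higher (16 over the list alone), such as CRIP1 (1.94 ± 0.34, camera adjusted p = 1.96e-10). Of 32 naive and quiescence genes 2 were higher and 9 lower (2 and 11 over the list alone), led by KLF2, which holds naive cells at rest (5.05 ± 2.19 against 20.5 ± 6.43 CPM, camera adjusted p = 0.000552, and adjusted p = 0.0886 with an estimated correlation). Cytokine genes had 7 higher and 3 lower (8 and 4 over the list alone, camera adjusted p = 0.0224, and adjusted p = 0.131 with an estimated correlation). T cell receptor signalling genes had 5 higher (9 over the list alone), such as PPP3CA, a calcineurin subunit (0.84 ± 0.12, camera adjusted p = 2.53e-06, and adjusted p = 0.0745 with an estimated correlation).

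Summed CD8 T cell markers stood at 34.7 ± 23.6 CPM in cord at 48 h against 4.92 ± 1.96 CPM, and CD4 at 267 ± 10.9 against 201 ± 14.5 CPM (adjusted p = 0.0396 each, exact permutation tests). By the same test and adjusted p, mitochondrial rRNA took 0.517% ± 0.0288 of the counts in cord and 0.342% ± 0.0683 in adult libraries, the 100 most abundant genes 21.5% ± 0.496 and 20.04% ± 0.561, and protein-coding genes 94.97% ± 0.612 and 96.2% ± 0.364. The test called 1187 genes, 709 higher and 478 lower in cord, 59.7% higher. With limma on TPM 698 were called and 41.3% were higher, length-scaled counts gave 728, a fit on the 48 h libraries alone 2489, and the fit without 6 libraries with outlying markers of other cells 733.

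**Figure D3:**
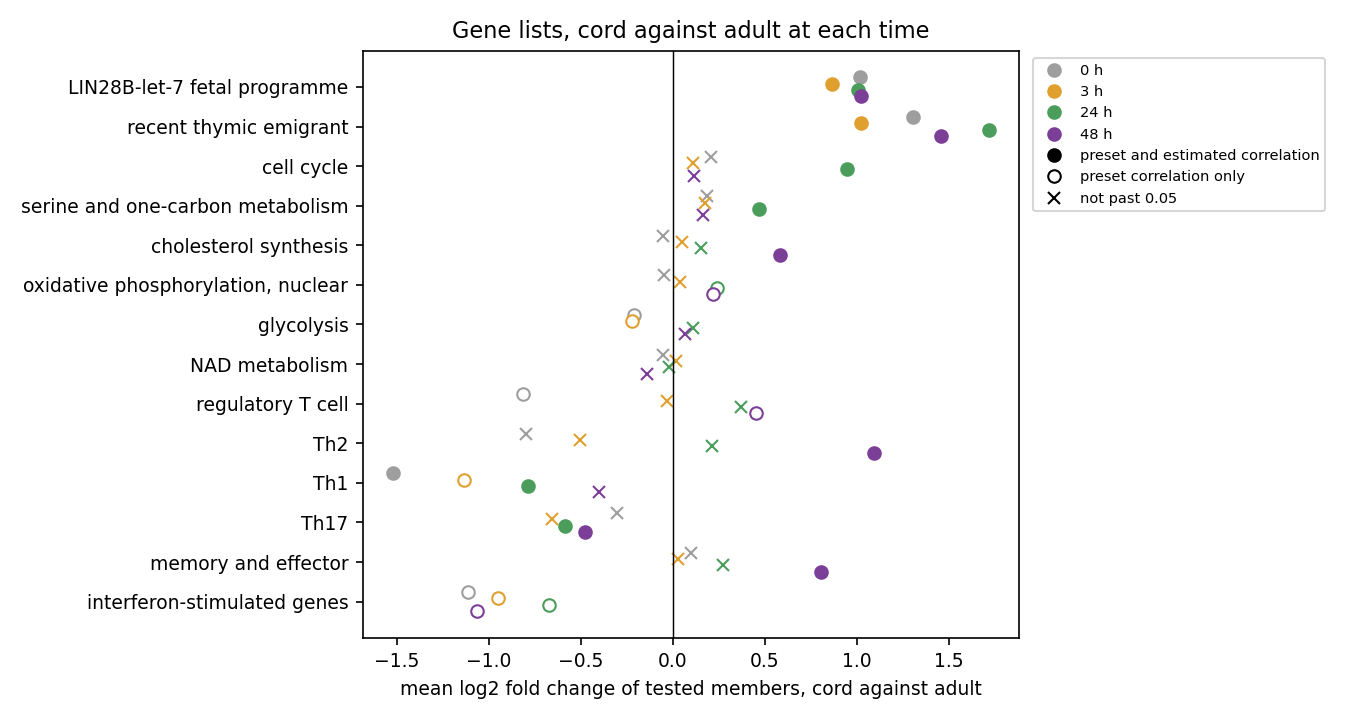
Mean log2 fold change of cord against adult (horizontal axis) over the tested members of 14 gene lists (vertical axis), coloured by hours after activation. Filled circles passed camera at both the preset and the estimated correlation, open circles at the preset correlation alone, and crosses at neither; the cell cycle list stands apart at 24 h and the Th2 and cholesterol lists at 48 h.

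At 3 h after activation early transcription factors and nutrient transporters were higher than at rest in cells of both sources. In cord cells EGR2, an early zinc-finger factor, went from 2.01 ± 1.20 CPM (n = 6) to 168 ± 74.2 CPM (n = 5), and IRF4, which scales with receptor signal, from 22.6 ± 10.2 to 1732 ± 527 CPM. In adult cells (n = 5 at each time) EGR2 went from 1.10 to 172 CPM and EGR3 from 2.97 to 452 CPM. SOCS3, a brake on cytokine signals, fell 39.7-fold in cord and 36.7-fold in adult cells, and GPA33, a surface protein of naive cells, fell 13.5-fold and 42.5-fold.

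Of 13 amino acid and iron transport genes 10 rose and none fell in cord (10 and 1 adjusted over the list alone, camera adjusted p = 7.51e-19), and 10 rose and none fell in adult cells (11 and 2, camera adjusted p = 2.52e-19). The leucine transporter SLC7A5 was up by 4.04 ± 0.32 and 4.64 ± 0.36. Immediate early genes had 23 up and none down in cord (24 and 1 over the list alone, camera adjusted p = 1.62e-19). There were 20 up and 2 down in adult cells (20 and 3, camera adjusted p = 1.79e-13, and adjusted p = 0.122 with an estimated correlation). NF-kB and survival genes had 18 up and 2 down in cord (the same counts over the list alone, camera adjusted p = 2.73e-13, and adjusted p = 0.0649 with an estimated correlation). There were 17 up and 3 down in adult cells (likewise over the list alone, camera adjusted p = 6.21e-07, and adjusted p = 0.244 with an estimated correlation). BCL2, which holds off apoptosis, was up by 4.35 ± 0.27 and 2.55 ± 0.26. Regulatory T cell genes had 12 up and 3 down in cord (the same over the list alone, camera adjusted p = 2.43e-06) and 9 up and 4 down in adult cells (10 and 4, camera adjusted p = 0.0209, and adjusted p = 0.244 with an estimated correlation). The TNF receptor TNFRSF18 led in cord (6.17 ± 0.54). CD38 did not pass in adult cells (-0.61 ± 0.28, adjusted p = 0.0924) and did so with a replicate block (-0.59, adjusted p = 0.0114). The test called 7631 genes in cord, 4362 up and 3269 down, and 7874 in adult cells, 4230 up and 3644 down.

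By 24 h cells of both sources had turned on cytokine, cell cycle and glycolysis genes. LIF, a cytokine of the IL-6 family, went from 0.163 to 386 ± 55.9 CPM in cord and from 0.480 to 445 ± 104 CPM in adult cells, and IL2 from 0.0889 to 112 ± 16.4 CPM and from 0.182 to 252 ± 49.3 CPM. GJB2, a gap junction protein with no counts in resting cord libraries, was at least 1020-fold higher at 24 h. SOCS3 stayed 24.6-fold below rest in adult cells, and IFIT1, an interferon-induced antiviral protein, fell 27.1-fold there. Its resting level varied widely between adult libraries (255 ± 301 CPM, against 9.42 ± 4.77 CPM at 24 h). In cord the IFIT1 mean was also lower at 24 h, at 4.34 ± 2.93 CPM against 75.8 ± 116 CPM at rest.

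Against rest, the median of all tested genes shifted by -0.21 (log2) in cord at 24 h and by -0.38 at 48 h, and by -0.16 and -0.34 in adult cells, so list medians at these times are given relative to it. The median of protein-coding genes alone shifted the other way, by 0.108 and 0.218 in cord and by 0.041 and 0.136 in adult cells. Against that baseline every relative median would be lower, with smaller rises and larger falls. Of 45 cell cycle genes 42 rose and 1 fell in cord (relative median 3.74, camera adjusted p = 8.66e-56) and 38 rose and 1 fell in adult cells (2.94, adjusted p = 5.09e-46), the same counts adjusted over the list alone. The replication factor MCM10 led both (8.19 ± 0.33 and 7.29 ± 0.35). Of 31 cytokine genes 27 rose and none fell in cord (27 and 0 over the list alone, relative median 4.53, camera adjusted p = 2.68e-08) and 20 rose and 2 fell in adult cells (21 and 3, 3.67, adjusted p = 1.32e-07). Of 25 glycolysis genes 19 rose and 4 fell in cord (20 and 4 over the list alone, relative median 1.60, camera adjusted p = 5.1e-12) and 16 rose and 4 fell in adult cells (17 and 4, 1.52, adjusted p = 1.66e-09). GAPDH stood at 2693 ± 398 CPM in cord and 2111 ± 445 CPM in adult cells. Of 77 oxidative phosphorylation genes 68 rose and none fell in cord (69 and 1 over the list alone, relative median 1.08, camera adjusted p = 6.74e-13, and adjusted p = 0.212 with an estimated correlation). In adult cells 51 rose and 2 fell (52 and 2, 0.76, adjusted p = 8.77e-09, and adjusted p = 0.341 with an estimated correlation). The electron carrier CYCS was up by 2.73 ± 0.16 and 2.05 ± 0.17. In adult cells 35 of 42 interferon-stimulated genes fell (36 over the list alone, relative median -2.19, camera adjusted p = 5.15e-05, and adjusted p = 0.52 with an estimated correlation). The mean of OAS1, an interferon-induced gene, was also lower at 24 h in cord (7.95 ± 4.24 against 84.0 ± 109 CPM at rest). The fall is so not shown to be particular to adult cells.

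CD38 was lower at 24 h than at rest in cord (-0.63 ± 0.26, adjusted p = 0.0447), a call that ended without the count filter, with length-scaled counts and in 10 of the 11 fits that left out a library. The test called 11959 genes in cord at 24 h, 6020 up and 5939 down, and 9941 in adult cells, 5166 up and 4775 down. On TPM, limma placed 36.7% of the cord calls up against 50.3% here.

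By 48 h proliferation genes had risen and quiescence genes had fallen in cells of both sources. MKI67 stood at 1095 ± 66.9 CPM in cord and 928 ± 84.0 CPM in adult cells, and PBK, a mitotic kinase with no counts at rest, was at least 2470-fold higher in cord and at least 1790-fold higher in adult cells. GZMB, a granzyme with no counts in resting cord libraries, was at least 1070-fold higher, and CD1C at least 1740-fold higher, in cord. KLF2 fell from 498 to 5.05 CPM in cord, and PIK3IP1, a brake on PI3 kinase, from 690.3 CPM (-5.43 ± 0.22).

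Of the cell cycle genes 44 rose and 1 fell in cord (relative median 5.67, camera adjusted p = 4.46e-57) and likewise in adult cells (5.75, adjusted p = 1.91e-62), the same counts adjusted over the list alone. Of 25 TCA cycle genes 24 rose and none fell in each source (24 and 0 over the list alone, relative medians 1.97 and 1.83, camera adjusted p = 1.79e-12 and 2.36e-11), with DLAT, of the pyruvate dehydrogenase complex, up by 3.12 ± 0.17 and 2.94 ± 0.18. Of 18 serine and one-carbon genes 14 rose and 1 fell in cord (2.77, camera adjusted p = 1.84e-08) and 13 rose and 1 fell in adult cells (2.75, adjusted p = 3.79e-09), the same over the list alone, with SHMT2 up by 4.07 ± 0.14 and 4.06 ± 0.16. Naive and quiescence genes had 6 up and 26 down in cord (-0.70, camera adjusted p = 1.85e-09) and 3 up and 23 down in adult cells (-0.64, adjusted p = 3.51e-09), the same over the list alone. Of 30 NAD genes 12 rose and 12 fell in cord (0.38, camera adjusted p = 0.464) and 13 rose and 8 fell in adult cells (0.41, adjusted p = 0.315), the same over the list alone. The NAD list medians themselves, 0.00 in cord and 0.07 in adult cells, lay below those of protein-coding genes (0.218 and 0.136). NAMPT, the rate-limiting enzyme of NAD salvage, was up by 3.24 ± 0.22 and 3.55 ± 0.24, and NMRK1, a nicotinamide riboside kinase, was down (-2.43 ± 0.29 and -2.46 ± 0.30). The test called 15773 genes in cord at 48 h, 7113 up and 8660 down, and 14291 in adult cells, 6525 up and 7766 down. On TPM, limma placed 28.7% of the cord calls up against 45.1% here.

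The response, meaning the log2 change from 0 h, was compared between the sources. A difference above 0 means a higher change in cord, through a larger rise or a smaller fall, and one below 0 a lower change, through a smaller rise or a larger fall. At 3 h the change was higher in cord for IL2RA and for the regulatory T cell and T follicular helper lists. IL2RA went from 2.30 ± 0.790 to 75.2 ± 28.8 CPM in cord and from 12.4 ± 5.53 to 25.8 ± 8.23 CPM in adult cells, a 15.7-fold larger change (log2 difference 3.97 ± 0.35, adjusted p = 2.98e-09). IGF2BP3 rose from 48.5 CPM in cord and went from 1.35 to 0.928 CPM in adult cells, a 7.44-fold difference of the changes. Of 24 regulatory T cell genes 5 had a higher and none a lower change in cord (8 and 2 adjusted over the list alone, camera adjusted p = 7.62e-06), and of 14 T follicular helper genes 4 a higher and 1 a lower change (the same over the list alone, camera adjusted p = 7.91e-05). Of the T follicular helper genes, CD200, an immune checkpoint ligand (1.80 ± 0.32), and the lineage factor BCL6 (1.69 ± 0.30) had higher changes in cord. NF-kB and survival genes had 2 above 0 (6 over the list alone, camera adjusted p = 0.000235, and adjusted p = 0.726 with an estimated correlation). CLIC3, an intracellular chloride channel, fell from 12.9 to 1.56 CPM in cord and stood at 1.03 CPM in resting adult cells (-2.98 ± 0.64, adjusted p = 0.00687). The test called 284 genes, 149 with a difference above 0 and 135 below 0. With the replicate block it called 603, with DESeq2 465, without the count filter 184, with limma on TPM 172, with length-scaled counts 169, on the groups compared alone 99 and without the 6 libraries 177.

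At 24 h the change was higher in cord for the regulatory T cell and cell cycle lists. IL2RA again rose more in cord (2.73 ± 0.35, adjusted p = 6.21e-06), and so did LRRC32, from 0.0448 to 33.7 CPM in cord and from 0.300 to 6.41 CPM in adult cells (4.99 ± 1.06, adjusted p = 0.00602, not past without the 6 libraries). The replication helicase gene MCM6 also rose more (1.41 ± 0.15, adjusted p = 1.95e-07). Of the regulatory T cell genes 6 had a higher and 1 a lower change in cord (10 and 1 adjusted over the list alone, camera adjusted p = 2.98e-06), and of the cell cycle genes 10 a higher and none a lower change (18 and 2 over the list alone, camera adjusted p = 1.57e-14). Glycolysis had 3 above 0 (7 and 1 below 0 over the list alone), with SLC2A3 at 1.19 ± 0.27, a smaller fall in cord (camera adjusted p = 0.000276, and adjusted p = 0.35 with an estimated correlation). Th2 genes had 4 above 0, also over the list alone (camera adjusted p = 0.00267, and adjusted p = 0.164 with an estimated correlation). Oxidative phosphorylation had 1 above 0 (0 over the list alone, camera adjusted p = 6.29e-07, and adjusted p = 0.446 with an estimated correlation). AHRR, a repressor of the aryl hydrocarbon receptor, went from 62.4 ± 58.2 to 63.6 CPM in cord and from 0.914 to 35.8 CPM in adult cells (-5.25 ± 1.05).

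TBK1, a kinase of innate signalling, headed the differences above 0 at 24 and 48 h (6.42 ± 0.81 and 6.52 ± 0.81), from 0.0555 CPM in resting cord and 6.10 CPM in resting adult libraries, but its reads at rest sat on 1 of its transcripts in an all-or-none way, so its gene level depends on the transcripts that could be matched. The test called 585 genes at 24 h, 393 with a difference above 0 and 192 below 0, 67.2% above. With limma on TPM 29.1% of 516 were above 0, DESeq2 called 922, no count filter 369, length-scaled counts 295, the groups compared alone 387 and the fit without the 6 libraries 349. Without cord replicate 1 at 24 h it called 361, without cord replicate 4 357, without adult replicate 5 303 and without adult replicate 6 322.

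At 48 h the change was higher in cord for the Th2, regulatory T cell and cholesterol synthesis lists. GATA3 went from 55.7 ± 7.34 to 237 ± 53.9 CPM in cord and from 43.4 ± 7.67 to 48.6 ± 10.2 CPM in adult cells (1.92 ± 0.23, adjusted p = 8.03e-07), MAF from 6.53 to 82.3 CPM and from 23.6 to 25.7 CPM (3.54 ± 0.40), and NFIL3 from 1.04 to 43.5 CPM in cord (3.59 ± 0.51). Of the Th2 genes 5 had a higher and none a lower change (5 and 0 adjusted over the list alone, camera adjusted p = 4.3e-12). IL13 was among them (6.36 ± 1.12, adjusted p = 0.000624, and adjusted p = 0.059 with the replicate block). Of the regulatory T cell genes 8 had a higher and 1 a lower change (10 and 1 over the list alone, camera adjusted p = 1.1e-07), such as IL2RA (2.79 ± 0.35) and TRIB1, which binds FOXP3 (3.37 ± 0.55). Of 24 cholesterol synthesis genes 8 had a higher change (14 over the list alone, camera adjusted p = 1.37e-14), such as DHCR7 (1.18 ± 0.24).

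Other groups followed at 48 h. Cytokine genes had 6 above 0 (11 and 1 below 0 over the list alone, camera adjusted p = 0.000724), such as OSM (3.75 ± 0.70). Memory and effector genes had 3 above and 1 below 0 (8 and 1, camera adjusted p = 4.08e-05), such as VIM (1.04 ± 0.25), and Th1 genes had 2 above 0 (3 and 1, camera adjusted p = 0.00149). Oxidative phosphorylation had 1 above 0, also over the list alone (camera adjusted p = 2.83e-06, and adjusted p = 0.54 with an estimated correlation). CD38 did not pass at 24 h (-1.16 ± 0.38, adjusted p = 0.108) or 48 h (-1.26 ± 0.38, adjusted p = 0.0741). At 48 h it passed with the replicate block (-1.27, adjusted p = 0.0179), with DESeq2 and with limma on TPM. The test called 536 genes at 48 h, 353 with a difference above 0 and 183 below 0, 65.9% above. With limma on TPM 31.4% of 567 were above 0, DESeq2 called 866, length-scaled counts 302 and the fit without the 6 libraries 280.

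**Figure D4:**
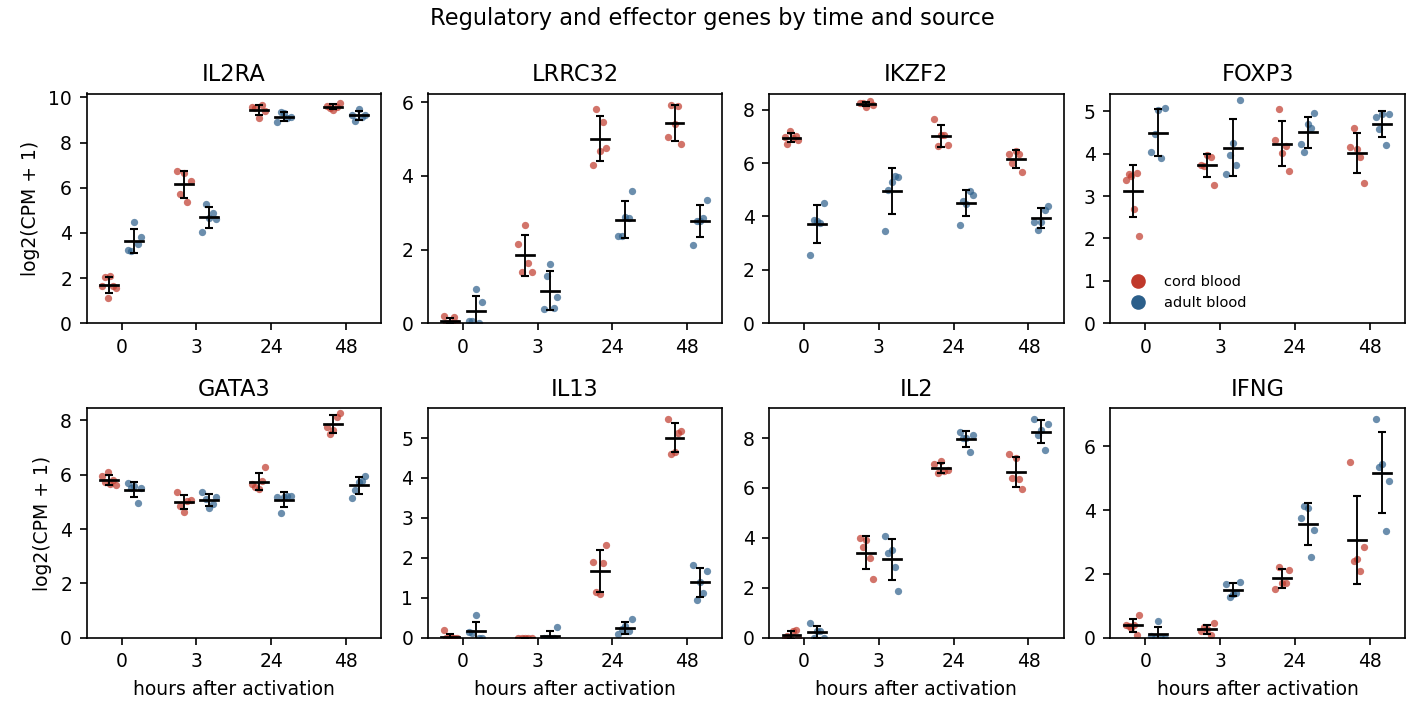
Levels of 8 genes as log2(CPM + 1) (vertical axes) against hours after activation (horizontal axes); points are libraries, lines group means and bars 1 SD. FOXP3 was chosen after its values were seen; LRRC32, IL13 and GATA3 lie higher in cord at 48 h, and IL2 lower.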

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

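The tests of the cytotoxic genes, of CD8A and CD8B and of the regulatory T cell list, and the count of other splits at 0 h were chosen only after the result was seen.

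Resting cord cells held FGFBP2 at 27.0 ± 12.7 CPM and GZMA at 15.4 ± 3.36 CPM, against 0.740 ± 0.714 and 0.636 ± 0.617 CPM in adult cells, and both genes are markers of cytotoxic cells. NK cells in the cord sort are argued against as the source of the whole difference. The other 11 tested members of the NK and cytotoxic list had a median log2 difference of -1.52 (SD 1.59), against 4.58 for the smaller of the 2 genes. Of the 11, GNLY alone was called (-1.91 ± 0.54), and the lowest, GZMB (-4.96 ± 1.84), had no counts in resting cord libraries. KLRD1 (0.17 ± 0.27), PRF1 (0.29 ± 0.425) and SPON2 (0.68 ± 0.24) lay above 0 but far below 4.58. CD8 T cells are argued against as the source of the whole difference, since CD8A stood at 0.429 CPM in cord and the larger log2 difference of CD8A and CD8B at rest was 1.41. A small share stays open, since the marker CRTAM was higher in cord (1.69 ± 0.51, adjusted p = 0.0199), as were the summed CD8 T cell markers (10.8 ± 3.60 against 4.30 ± 2.38 CPM, exact test, adjusted p = 0.0396). What stays open is expression of these genes by naive CD4+ T cells of cord blood, which may be a property of the source and was not tested, and the sort was for naive CD4+ T cells.

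CD8B stood at 25.6 ± 15.95 CPM in cord and 4.86 ± 3.02 CPM in adult cells at 24 h (2.39 ± 0.54 on the log2 scale), and CD8A at 7.81 ± 8.50 and 0.525 ± 0.696 CPM (3.83 ± 1.10). A fixed share of CD8 T cells, each with a constant level of these genes, is argued against, since CD8B rose by 2.70 ± 0.51 and CD8A by 4.13 ± 1.04 in cord between 0 and 24 h. For CD8B 1 library is argued against as the whole cause, since the lowest log2 difference without a library was 2.005 (without cord replicate 1 at 24 h, adjusted p = 0.016) and the gene passed in all 10 fits. For CD8A it stays open, since without the same library the call ended (adjusted p = 0.121) while the difference, 2.899, stayed within 1 SE of the full value, and the 4 other fits that ended the call each left out an adult library and gave 3.53 at the least. A larger share of CD8 T cells in the libraries at later times, or CD8 expression by activated CD4+ T cells of cord blood, may each be the source, and neither was tested.

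The regulatory T cell list had a higher change from rest in cord at 3 h (camera adjusted p = 7.62e-06), at 24 h (adjusted p = 2.98e-06) and at 48 h (adjusted p = 1.1e-07), which marked it as a difference between groups in the change with time. Within donors the list stayed past the threshold at 24 and 48 h, with a larger adjusted p of 7.32e-05 (camera). This argues against different donors at these times as the whole cause, for the donors it covers. Only 2 adult and 4 cord donors had libraries both at 0 h and at 24 or 48 h. The p-value compares the list with other genes and does not measure the spread between donors. A lower resting level in cord as the only cause stays open: of 8 members with a larger rise at 48 h, 6 were lower in cord at rest (IL2RA, CTLA4, RTKN2, TRIB1, BATF and PRDM1) and 2, LRRC32 and IL10, were higher in cord at 48 h. The larger rise may so be in part a return to the adult level, and a biological difference between the sources in the change itself was not tested apart from it.

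Other results were marked because the change with time differed between the sources by a test of that difference. The counts of such genes were 284 at 3 h, 585 at 24 h and 536 at 48 h. By list the adjusted p was 7.91e-05 for T follicular helper genes at 3 h and 1.57e-14 for cell cycle genes at 24 h. At 48 h it was 1.37e-14 for cholesterol synthesis, 4.3e-12 for Th2, 4.08e-05 for memory and effector, 0.000724 for cytokine and 0.00149 for Th1 genes.

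The genes with the most unequal changes at 3 h, as log2 differences of cord against adult, were TNFSF14 (4.90), IL2RA (3.97), MARCKS (3.23), IGF2BP3 (2.90) and SECTM1 (2.85) above 0. Below 0 were EGR4 (-5.14), CLIC3 (-2.98), TNFRSF12A (-2.81), RASL10B (-2.79) and PDLIM7 (-2.75). At 24 h they were TBK1 (6.42), GJB2 (5.56), LRRC32 (4.99), IL1A (4.63) and TNFSF14 (4.54), and AHRR (-5.25), MIR4432HG (-4.41), TNFSF11 (-3.77), ADGRG5 (-3.64) and CHRNA6 (-3.53). At 48 h they were TBK1 (6.52), IL13 (6.36), KIAA1217 (6.22), CCL2 (6.20) and TMEM273 (6.11), and AHRR (-5.03), DGKI (-4.67), CALML3-AS1 (-4.03), CLIC3 (-3.96) and ADGRG5 (-3.90). EGR4 had no counts in resting adult libraries and GJB2 and KIAA1217 none in resting cord libraries, so their values depend on the prior count and are no bounds. TNFSF14, TNFRSF12A, LRRC32, IL1A, TNFSF11, IL13, TMEM273 and DGKI had resting means of at most 0.728 CPM in either source. Their values so rest in part on few resting counts. MIR4432HG, ADGRG5, CALML3-AS1 and CLIC3 fell in cord from 10.3, 11.3, 6.69 and 12.9 CPM at rest. In resting adult cells they stood at 0.755, 0.622, 0.440 and 1.03 CPM, which left less room for a fall. CCL2 varied widely between resting adult libraries (8.96 ± 9.86 CPM). For TBK1 the gene level depends on the transcripts that could be matched. TNFSF14 stood at 15.01 CPM in cord and 11.1 CPM in adult cells at 3 h, and at 47.46 and 45.16 CPM at 24 h. LRRC32 did differ in level at 24 h (33.7 against 6.414 CPM).

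Libraries far from the others of their group were sought in 136 groups of other measures (markers of other cells, CD4, and shares and totals of counts) and 8 groups of CD38, and chance gives about 1 in 20. There were 11 among the former. Summed erythroid markers stood at 94.0 CPM in adult replicate 7 at 0 h and 51.6 CPM at 3 h, and at 87.4 CPM in cord replicate 5 at 24 h and 12.7 CPM at 48 h. Fetal haemoglobin genes stood at 21.5 and 1.70 CPM in these 2 cord libraries. CD8 T cell markers were at 76.2 CPM in cord replicate 1 at 48 h, monocyte markers at 30.2 CPM in cord replicate 7 at 0 h, granulocyte markers at 2.45 CPM in cord replicate 4 at 24 h, progenitor markers at 1.03 CPM in adult replicate 5 at 48 h and CD4 at 131 CPM in cord replicate 6 at 3 h. CD38 in adult libraries at 48 h had 1 library apart, at 46.3 CPM. A signal outside the genes tested was the share of counts on transcripts that matched no gene, at a median of 11.5% of a library.

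In each of the 13 comparisons 1 of 100 splits of the same libraries, the real one, gave as many genes. This argues against chance as the source of the counts, but so few splits cannot exclude it. Adult libraries at 3 h have too few splits that keep their pairing to decide. Between the sources the real split called 3113 genes at 0 h and the highest other 2506, with 2574 and 2224 at 3 h, 1897 and 134 at 24 h, and 1187 and 19 at 48 h. For the difference of changes the counts were 284 and 119 at 3 h, 585 and 78 at 24 h, and 536 and 3 at 48 h, where donors kept their times and the source moved between donors. Against rest, cord libraries gave 7631 at 3 h against 5524 in the highest of 31 splits that part as many donor pairs (5), 11959 at 24 h against 9859 in 47 (4 pairs), and 15773 at 48 h against 13478 in 47 (4 pairs). Adult libraries gave 7874 at 3 h against 3060 in 15 (5 pairs), too few for a share under 0.05. They gave 9941 at 24 h against 4597 in 39 (2 pairs), and 14291 at 48 h against 7842 in 39 (2 pairs). The other splits part fewer donor pairs, and the highest among them were 4219, 9490 and 8757 in cord and 5114, 4710 and 8103 in adult libraries.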

How the results depend on the processing

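The fit without 6 libraries with outlying markers of other cells and the fit by limma-voom with no block were chosen only after the result was seen. Every count below is of genes past an adjusted p of 0.05, and the cause was not tested unless it is given.

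The counts of genes changed between times (6 comparisons) stayed within 1.5 times their value under each alternative. RLE size factors left every count of the 13 comparisons and the 190 list tests past the threshold within that range. A fit on the groups compared alone changed the spread, the normalisation and the genes past the count filter together. It called 1754 genes at 0 h (3113 in the fit to all), 1381 at 3 h (2574), 2902 at 24 h (1897) and 2489 at 48 h (1187) between the sources, and 99 at 3 h (284) and 387 at 24 h (585) in the difference of changes. Between the sources the counts so fell from 0 to 48 h in the fit to all, while the fits alone called most genes at 24 h. A trend of the source difference with time therefore depends on the fit.

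With limma on TPM the counts between the sources were 1653 at 3 h, 1243 at 24 h and 698 at 48 h, and 172 in the difference of changes at 3 h. Counts scaled by transcript length gave 1130 and 728 between the sources at 24 and 48 h, and 169, 295 and 302 in the difference of changes at 3, 24 and 48 h. DESeq2 called 465, 922 and 866 genes there, and no count filter, which adds genes to the adjustment, 184 at 3 h and 369 at 24 h. Without the 6 libraries, so with fewer samples, the counts were 733 between the sources at 48 h and 177, 349 and 280 in the difference of changes. The share of genes higher in cord also turned with limma on TPM, to 34.9% from 60.5% at 24 h and to 41.3% from 59.7% at 48 h. That setting changed the test, the gene filter and the normalisation together with the unit. With length-scaled counts, made from the same TPM and tested with edgeR, the share was 61.5% and 60%. The unit alone is so not shown to turn the share.

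With the replicate block, which compares times within donors, the difference of changes at 3 h called 603 genes against 284. The paired fit changed no other count by over 1.5 times and kept each of 92 list tests on its side of the threshold. Among 486 named gene values it left 444 on their side, 38 fell below the threshold and 4 passed it. Limma-voom with no block left the 4 counts between the sources within 1.5 times.

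With a correlation estimated from the data 82 list tests passed (73 upward and 9 downward) against 190 at the preset correlation of 0.01 (149 and 41). Of the 92 list tests described, 32 fell below the threshold this way. With fry, a test of whether a list moves on balance, 12 fell below and 3 passed.

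Leaving out 1 library at a time gave 303 to 632 genes in the difference of changes at 24 h. The count was 361 without cord replicate 1 and 357 without cord replicate 4 at 24 h, and 303 without adult replicate 5 and 322 without adult replicate 6 at 24 h. The CD38 difference ranged from 0.422 to 0.983 at 24 h, where it passed the exact test without adult replicate 3 (0.983), and from 0.203 to 0.494 at 48 h, where it passed without cord replicate 5 (0.494). At 0 and 3 h it ranged from 1.54 to 1.86 and from 0.908 to 1.12. Shares by direction moved too. Without adult replicate 6 at 24 h 62.2% of the genes changed from rest in adult cells were up against 52.0%, and in the difference of changes at 3 h 36.1% were above 0 without cord replicate 1 and 40.8% without adult replicate 8, against 52.5%.

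For named genes, limma on TPM kept 406 of 475 values on their side, with 64 below the threshold, 4 past it and 1 reversed, TNFSF11 in the difference of changes at 24 h (0.219, adjusted p = 0.794, against -3.77). TNFSF11 stood at most at 0.421 CPM at rest, so its log2 change rests on few counts. Length-scaled counts kept 426 of 486, no filter 458, the groups compared alone 438 of 480, the fit without 6 libraries 451 and DESeq2 483 of 485. Genes below the count filter were not tested, so nothing is said of them at this depth. In simulated data with the numbers and depth of these libraries, but without donor effects, 2-fold differences of changes were found in 56% of cases. These genes had a mean of at least 5 CPM.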

Other observations

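Antioxidant, fatty acid, inhibitory receptor and TGF-beta genes also changed from rest after activation, on balance in the same direction in both sources. Genes of antioxidant defence rose by 48 h, 21 of 24 in cord with none falling (21 and 0 adjusted over the list alone, relative median 2.51, camera adjusted p = 5.16e-12) and 20 with 1 falling in adult cells (21 and 1, 2.24, adjusted p = 1.48e-11). PRDX1, a peroxiredoxin, went from 47.7 to 848 ± 43.9 CPM in cord and from 50.7 to 797 ± 42.0 CPM in adult cells. Of 25 fatty acid oxidation genes 18 rose and 1 fell in cord at 48 h (19 and 1 over the list alone, relative median 1.48, camera adjusted p = 0.000221), such as ETFA (2.46 ± 0.13), and 19 rose and 3 fell in adult cells (19 and 3, relative median 1.496, adjusted p = 0.000582, and adjusted p = 0.05 with an estimated correlation, which is not under the threshold).

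Of 31 inhibitory receptors and attenuators of the T cell receptor 15 rose and 2 fell in cord by 3 h (16 and 2 over the list alone, camera adjusted p = 2.43e-06), and 11 rose and 4 fell in adult cells (11 and 4, adjusted p = 0.000611). PDCD1, which encodes PD-1, led both (5.40 ± 0.73 and 4.68 ± 0.75). Of 25 TGF-beta genes 4 rose and 12 fell in cord by 24 h (5 and 13 over the list alone, relative median -0.29, camera adjusted p = 0.00369), and 5 rose and 13 fell in adult cells (6 and 14, -0.36, adjusted p = 0.0202, and adjusted p = 0.113 with an estimated correlation). PMEPA1, a brake on TGF-beta signals, fell in both (-3.46 ± 0.30 and -2.49 ± 0.30), while TGFBR3, a TGF-beta co-receptor, rose in cord (4.56 ± 0.26) and did not pass in adult cells (0.09 ± 0.23), a difference of 4.47 ± 0.34 (adjusted p = 1.87e-11).

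Across the 23190 genes tested, the change in cord and the change in adult cells correlated with r = 0.673 (rho = 0.689) at 3 h, 0.797 (0.793) at 24 h and 0.876 (0.882) at 48 h. These are correlations across genes, which are not independent replicates, and both changes rest on noise of their own resting libraries. Of 5686 genes past the threshold in both sources at 3 h 99.35% changed in the same direction, and 37 in opposite directions. At 24 h it was 27 of 8371 and at 48 h 59 of 12551.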
